A study of Homo sapiens with 51 samples.

How the data were processed

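Values came from the deposited table of log2 RPKM, with gene symbols and 51 columns named after the samples. The submitters' notes name STAR for alignment, HTSeq for counting and the human genome hg19, without versions or options. RNA was taken with Trizol and a column with DNase, depleted of ribosomal RNA and made into stranded total RNA libraries. A further table of whole numbers has 81 unnamed columns and was not used here, since no column can be matched to a sample by name.

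The table was made by the authors in 3 parts, each with its own gene filter, library scaling and offset before the logarithm. These are the 15 libraries of DMSO and 80 nM (21700 genes, offset 2.03 reads), the 24 libraries of the duplexes (19777 genes, offset 2.0 reads) and the 12 libraries of 100 to 500 nM (23098 genes, offset 2.1 reads). Inside a part the lowest value of a gene is the same in every library with 0 reads, and values rise from it in equal steps on the linear scale. Whole reads were recovered from those steps for 100.0% of values, with a largest distance from a whole number of 3.8e-08. Of 21041 symbols shared by the DMSO and dose parts, 3 had lengths that differed by more than 0.01 in log2, and their parts were not joined. Libraries held 7897060 to 15662385 reads in listed genes, and the top gene took 2.41 to 11.6% of them. Comparisons of 100 to 500 nM with DMSO join separately processed parts, where a batch difference cannot be separated from the treatment by those libraries alone. So does the side test of scramble against DMSO libraries at day 2, and so does the alternative with all 51 libraries in 1 fit. The other comparisons lie inside a part.

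The design had assumed counts and a test for counts. The named table is in log2 units, and the test used was limma 3.58.1 in R 4.3.3 on log2 CPM (reads scaled to library size) of the recovered reads, with an intensity trend and robust variance moderation (statmod 1.5.0). A prior count of 2 was added. Libraries were scaled by a trimmed mean of log ratios computed from the reads, with 30% of log ratios and 5% of mean levels trimmed on each side. Genes were kept with the equivalent of 10 reads in at least 3 libraries and 15 reads in all. Genes absent from a part are missing in its libraries, and a gene was tested only where every library of the fit held it. The list of comparisons, the test threshold, the naming rule, the gene lists and the main alternatives were fixed before the data were examined.

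Group means were fitted in 5 models. The day 2 drug model held 18 libraries in 6 groups (DMSO of both lines and 4 doses), the washout model 9 libraries in 3 groups, each day of the duplex experiment 12 libraries in 4 groups, and the comparison of days 24 libraries in 8 groups. From these came 20 comparisons with n = 3 libraries per group. They are HMLE-TWIST1 against HMLE in DMSO and scramble at each day, each dose against DMSO, steps between doses, washout against DMSO, knockdown against scramble in each line and day, the difference of the knockdown effect between lines, and its difference between days. Adjusted p is the Benjamini-Hochberg value over all genes tested in a comparison, with a threshold of 0.05. Log2 fold changes carry the standard error of the moderated fit.

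Named genes are TWIST1, SUV39H1 and SUV39H2, the markers CDH1, EPCAM, CDH2, VIM, FN1, ZEB1 and SNAI2, the 5 largest rises and falls in each comparison, and up to 4 members of each list with the smallest adjusted p. Largest rises and falls had an average log2 CPM of at least 2 and no overlap between groups. Genes whose control holds only a few reads are given as reads and CPM.

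There were 26 gene lists written from general knowledge. They cover epithelial, mesenchymal, mammary basal and mammary luminal genes, transcription factors of the transition, H3K9 methylation and heterochromatin, interferon-stimulated genes, NF-kB and cytokines, NRF2 and thioredoxin, heat shock, ATF4 and the unfolded protein response, p53 targets, mitosis, DNA replication, replication-dependent histones, TGF-beta response, immediate early genes, cholesterol synthesis, apoptosis regulators, germline genes, zinc finger genes, ribosomal proteins, mitochondrially encoded genes, and leukocyte, endothelial and adipocyte markers. The mitochondrially encoded list had 0 symbols in the table. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, and again with a correlation estimated from the residuals, and with fry. Adjusted p for lists is over the lists of a comparison. Of 488 list tests 205 passed with the preset correlation, 48 of these with an estimated correlation and 176 with fry. TWIST1 was left out of the lists between the lines, and SUV39H1 and SUV39H2 in the knockdowns.

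Sets that separate the lines were genes with an absolute log2 fold change of at least 1 past the threshold in control libraries outside the comparison followed. Their medians were compared with 1000 draws of genes matched for abundance, a step added after the results were seen. Overlaps were compared with the number expected from independent calls. The overlaps that involve the washout were added after the results were seen.

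A pairing check asked whether libraries that share a replicate number resemble each other, with r of at least 0.1 for every number. It passed for HMLE-TWIST1 against HMLE in DMSO at day 2 (r = 0.142 to 0.184) and day 4 (0.113 to 0.194) and for the steps between doses (0.625 to 0.771, 0.647 to 0.852 and 0.498 to 0.732). The replicate block is an added term for the replicate number.

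Alternatives written before the data were examined were median-of-ratios scaling, no filter on low counts, only the compared groups in the fit, all 51 libraries in 1 fit, the replicate block, and leaving out each library in turn. Added later were precision weights (voom), prior counts of 0.5 and 8, the deposited log2 RPKM as given for comparisons outside the day 2 drug model, and a fit of the dose libraries alone. On simulated reads with 200 changed genes of at least 30 mean reads, the share of calls at unchanged genes was 3.5 to 7.6%. For 500 against 200 nM, 28.4% of 1.5-fold, 73.1% of 2-fold and 93.9% of 4-fold changes were found. Simulated libraries were independent, with a spread averaged over the groups of the fit. The dose libraries share replicate structure, and the spread of some exceeded that of DMSO libraries. The shares found may therefore be too high for the doses. Spread between replicates exceeded counting noise, with chi-square per degree of freedom of 2.14 to 40.7 and a median of 9.34 over groups.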

Results

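HMLE cells are immortalised human mammary epithelial cells, and HMLE-TWIST1 cells carry the transcription factor TWIST1, which drives epithelial to mesenchymal transition. TWIST1 reads were counted per gene, so an introduced copy and the cell's own gene cannot be told apart in its changes. Total RNA was measured in 51 libraries from 17 groups of 3, and levels are given as reads scaled to library size (CPM). Mesenchymal HMLE-TWIST1 cells received chaetocin, a fungal inhibitor of the histone H3 lysine 9 methyltransferases SUV39H1 and SUV39H2, for 48 h at 100 to 500 nM. Another group received 80 nM for 15 h and then 48 h of fresh medium. Both lines also received small interfering duplexes against SUV39H1 and SUV39H2, or a scrambled duplex, and were taken at day 2 or day 4. Day 2 followed 48 h with the duplex, and day 4 a further 48 h of recovery. DMSO cells of day 4 had 15 h of DMSO and 48 h of recovery. Nothing in the sample records says that replicates were separate cultures, so every p measures only the spread between these samples.

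In the DMSO cells of day 2, TWIST1 RNA was higher in the HMLE-TWIST1 line by a log2 fold change of 6.68 (SE 0.23, adjusted p = 7.4e-13, n = 3 libraries per line), from 5.65 ± 0.51 (SD) to 601.5 ± 84.9 CPM. VIM, which encodes the intermediate filament vimentin, was higher by 7.58 (SE 0.19, adjusted p = 7.6e-15), and ZEB1, a repressor of epithelial genes, by 8.03 (SE 0.23, adjusted p = 7.7e-14). CDH2, for N-cadherin, was higher by 4.26 (SE 0.37, adjusted p = 1.3e-07). FN1, the matrix glycoprotein fibronectin, was higher by 3.39 (SE 0.49, adjusted p = 3.8e-05), and SNAI2, another epithelial repressor, by 1.45 (SE 0.13, adjusted p = 6.4e-08). CDH1, for the adhesion molecule E-cadherin, had 3 reads in the HMLE-TWIST1 libraries against 21951 in HMLE (0.0916 against 596 CPM, adjusted p = 9.2e-12). EPCAM, an epithelial surface protein, had 1 read against 3215 (adjusted p = 5.2e-13). The basal genes COL17A1, a hemidesmosomal collagen, and TP63, a transcription factor of basal cells, were lower at -10.41 (SE 0.35) and -10.38 (SE 0.40).

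Of 39 epithelial genes measured, 39 were lower and 0 higher in HMLE-TWIST1 DMSO cells at day 2, with a median of -6.74 (camera adjusted p = 5.2e-30, and 0.00012 with an estimated correlation). Among them was CDH3, for P-cadherin (-9.25). Of 38 mesenchymal genes 36 were higher and 1 lower, with a median of 4.95 (adjusted p = 3.4e-20). With an estimated correlation this adjusted p was 0.108, and 0.0365 with the replicate block. The fibrillar and microfibrillar collagens COL5A1 (982.1 against 0.0299 CPM) and COL6A2 (1087 against 0.856) led that list. Luminal genes were lower (9 of 12, 1 higher, median -2.35, adjusted p = 0.00028, and 0.0128 with an estimated correlation). Of 17 basal genes 11 were lower and 4 higher, with a median of -9.17 (adjusted p = 2.2e-05, and 0.146 with an estimated correlation). Of 14 transcription factors of the transition, TWIST1 left out, 8 were higher and 3 lower, with a median of 1.32 (adjusted p = 0.0257, and 0.462 with an estimated correlation). Genes past an adjusted p of 0.05 numbered 4535 higher and 4371 lower of 18801 tested.

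SUV39H2 was higher in HMLE-TWIST1 cells at day 2 in DMSO (log2 fold change 1.18, SE 0.14, adjusted p = 1.9e-06, n = 3 libraries per line), with 40.7 against 17.8 CPM. SUV39H1 did not pass (0.27, SE 0.17, adjusted p = 0.222), and passed without replicate 2 of HMLE-TWIST1 DMSO day 2 (0.45, adjusted p = 0.0454). In the DMSO cells of day 4 both were higher, SUV39H1 by 1.32 (SE 0.17, adjusted p = 5.5e-06) and SUV39H2 by 2.10 (SE 0.15, adjusted p = 1.9e-08). In scramble cells SUV39H1 was higher by 1.00 (SE 0.19) at day 2 and 1.46 (SE 0.26) at day 4, and SUV39H2 by 2.39 (SE 0.13) and 2.61 (SE 0.11). Of 25 genes of H3K9 methylation and heterochromatin 10 were higher and 3 lower in DMSO at day 2 (10 and 4 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.402).

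**Figure D1:**
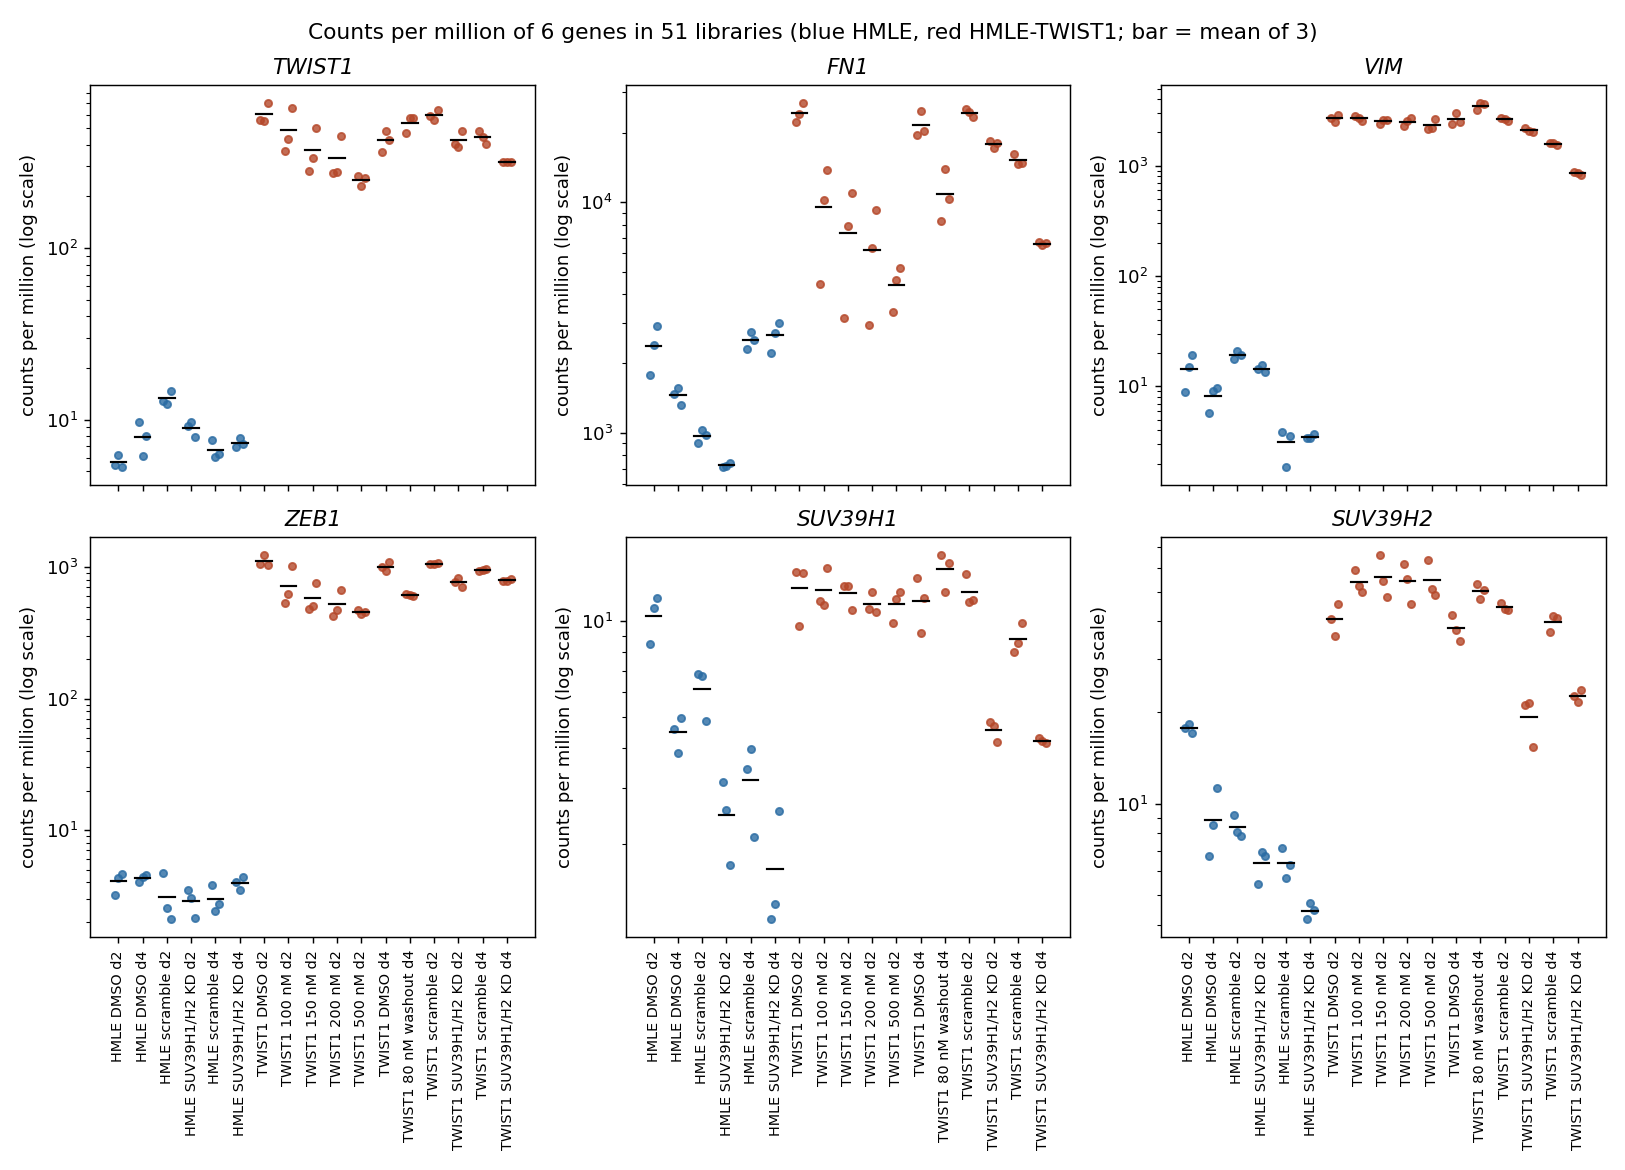
Levels (CPM) of TWIST1, FN1, VIM, ZEB1, SUV39H1 and SUV39H2 in each library of the 17 groups on a logarithmic axis. Points are libraries and bars are means of 3.

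The contrast between the lines was larger in the scramble cells of day 4, with 6762 genes higher and 6622 lower of 17985. KRT14, a basal keratin, stood at 0.0925 against 2738 CPM, and KRT6A, a keratin of activated epidermis, at 0.14 against 5706 (n = 3 libraries per line). CDKN1A, for the cell cycle inhibitor p21, was lower (log2 fold change -3.85, SE 0.06, adjusted p = 6.5e-19), at 86.8 against 1257 CPM. MKI67, a marker of cycling cells, was higher by 3.84 (SE 0.07) and CCNB1, for cyclin B1, by 3.73 (SE 0.07). All 27 mitosis genes were higher, with a median of 3.73 (camera adjusted p = 0.0276 with an estimated correlation). Among 60 histone genes 57 were higher and 1 lower (median 3.52, 0.0276 with an estimated correlation). In the DMSO cells of day 2 only 1 mitosis gene was higher and 0 lower (median -0.01, camera adjusted p = 0.836). Ribosomal protein genes were also higher at day 4 in scramble cells (75 of 82, median 0.60, adjusted p = 2.6e-09, and 0.165 with an estimated correlation). Cholesterol synthesis genes were lower there (16 genes, median -1.10, adjusted p = 3.3e-05, and 0.144 with an estimated correlation).

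The DMSO cells of day 4 and the scramble cells of day 2 gave 5890 genes higher and 5879 lower of 17585, and 6390 higher and 5957 lower of 17888. KRT13, a keratin of stratified epithelium, had 0.0262 against 3232 CPM in DMSO at day 4 and 0.0231 against 3161 in scramble cells at day 2 (n = 3 libraries per line). FN1 was higher by a log2 fold change of 3.89 (SE 0.18) and 4.66 (SE 0.05), and ZEB1 by 7.81 (SE 0.07) and 8.42 (SE 0.27). In DMSO cells of day 4 the epithelial list passed with an estimated correlation at an adjusted p of 0.0301, against 0.0714 with the replicate block. All 27 mitosis genes were higher in DMSO at day 4 (median 2.21, camera adjusted p = 4.7e-12, and 0.304 with an estimated correlation). In scramble cells of day 2, 26 of 27 were higher (median 1.83, camera adjusted p = 1.7e-12, and 0.0224 with an estimated correlation).

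At 500 nM chaetocin for 48 h, TWIST1 RNA fell (log2 fold change -1.26, SE 0.23, adjusted p = 0.00033, n = 3 libraries per group), from 601.5 ± 84.9 to 250.1 ± 16.5 CPM. FN1 fell (-2.50, SE 0.49, adjusted p = 0.00076), as did ZEB1 (-1.27, SE 0.23, adjusted p = 0.00025) and SNAI2 (-1.02, SE 0.13, adjusted p = 1.1e-05). COL1A2, a chain of type I collagen, fell (-4.15, SE 0.69, adjusted p = 0.00019), as did PDGFRB, a growth factor receptor of mesenchymal cells (-3.78, SE 0.43, adjusted p = 7.8e-06). VIM (-0.21, SE 0.19, adjusted p = 0.377) and CDH2 (0.02, adjusted p = 0.971) did not pass. CDH1 rose from 3 to 77 reads, or from 0.0916 to 2.60 CPM (adjusted p = 6.1e-05), where HMLE DMSO cells had 596. EPCAM rose from 1 to 36 reads (0.0281 to 1.22 CPM, adjusted p = 4.9e-06). ESRP1, a splicing regulator of epithelial cells, rose from 1 read to 84 (adjusted p = 7.7e-06), and LAMB3, a laminin chain, rose by 4.72 (SE 0.54, adjusted p = 7.5e-06). Gains from a few reads were not particular to epithelial genes. The 1083 genes silent in DMSO cells of day 4 gained 34.6 times in read density at 500 nM, in a set whose filter favours gains.

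Of 38 mesenchymal genes 28 fell and 2 rose at 500 nM, with a median of -1.67 (camera adjusted p = 7.5e-08). With an estimated correlation that adjusted p was 0.322. COL5A1 (-2.85), SPARC, a collagen-binding matrix protein (-2.34), and the surface glycoprotein THY1 (-2.32) were among them (n = 3 libraries per group). Of 39 epithelial genes 17 rose and 4 fell, with a median of 0.76 (adjusted p = 0.00817, and 0.285 with an estimated correlation). Basal genes split, 6 up and 6 down of 17 (median 0.21, adjusted p = 0.815). TP63 rose from 5 to 113 reads and COL17A1 from 13 to 224, while KRT5, a basal keratin, went from 79 to 9 reads. Luminal genes gave 4 up and 1 down of 12 (median 0.09, adjusted p = 0.51). The transition factors gave 4 up and 6 down of 15, with median -0.09 and mean -0.19 (adjusted p = 0.51). SUV39H1 RNA did not pass (-0.14, adjusted p = 0.516). SUV39H2 was higher by 0.42 (SE 0.14, adjusted p = 0.0208), a call lost without DMSO replicate 1 (0.0509) or 2 (0.104) or 500 nM replicate 1 (0.111). The H3K9 methylation list gave 4 up and 8 down of 25 (median -0.15, adjusted p = 0.515). KDM4D, a demethylase of that mark, rose by 2.07, and CBX5, for the heterochromatin protein HP1 alpha, fell (-0.95).

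At 500 nM chaetocin IL8, a neutrophil chemokine, rose by a log2 fold change of 8.53 (SE 1.02, adjusted p = 1.2e-05, n = 3 libraries per group), from 1.06 ± 0.41 to 590.5 ± 416.6 CPM. HDAC9, a histone deacetylase, rose by 6.27 (SE 0.57, adjusted p = 1.3e-06). FER1L6, a ferlin of unknown role, rose from 6 to 1365 reads (adjusted p = 4.7e-09), and LRP1B, a lipoprotein receptor, from 2 to 494 reads (adjusted p = 3.0e-08). HMOX1, heme oxygenase and a target of NRF2, rose by 4.54 (SE 0.34, adjusted p = 2.1e-07). FOSL1, a subunit of AP-1, rose by 3.87 (SE 0.28, adjusted p = 1.0e-07). GDF15, a stress cytokine induced by p53, rose by 4.44 (SE 0.44, adjusted p = 1.8e-06), and PMAIP1, a pro-apoptotic protein, by 2.85 (SE 0.24, adjusted p = 3.0e-07).

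NF-kB and cytokine genes rose at 500 nM in 19 of 21 cases with 0 falls (20 adjusted over the list alone), with a median of 3.65 (camera adjusted p = 1.1e-08, and 0.306 with an estimated correlation). IL6, an inflammatory cytokine, rose by 5.33 and RELB, an NF-kB subunit, by 2.76 (n = 3 libraries per group). Immediate early genes gave 17 of 20 up, 0 down (median 1.65, adjusted p = 2.3e-07, and 0.285 with an estimated correlation). NRF2 and thioredoxin genes gave 16 up and 3 down of 24 (median 1.12, adjusted p = 0.00013, and 0.285 with an estimated correlation), and TXNRD1, thioredoxin reductase, rose by 1.15. Heat shock genes gave 13 up and 3 down of 18 (median 0.83, adjusted p = 0.00293, and 0.467 with an estimated correlation). Mitosis genes gave 19 up and 0 down of 27 (median 0.64, adjusted p = 0.00019, and 0.586 with an estimated correlation). Targets of p53 gave 7 up and 1 down of 22 (median 0.52, adjusted p = 0.0166, and 0.816 with an estimated correlation). Cholesterol synthesis genes gave 15 down and 1 up of 21 (median -0.83, adjusted p = 5.3e-05, and 0.306 with an estimated correlation).

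Few genes of other lineages passed the abundance filter at 500 nM, with 4 of 29 germline, 3 of 14 leukocyte, 4 of 11 endothelial and 5 of 9 adipocyte genes, of which 4, 2, 3 and 1 rose. Genes near 0 reads in DMSO cells enter through the dose libraries, which favours rises, so these lists were not read as sets. DDX4, a germ cell helicase, went from 2 to 74 reads (adjusted p = 2.6e-05, n = 3 libraries per group) and PIWIL2, a small RNA partner, from 4 to 76 (3.7e-06). PTPRC, for the leukocyte antigen CD45, went from 2 to 88 reads, ITGAM, an integrin of myeloid cells, from 2 to 234 and ERG, an endothelial transcription factor, from 10 to 234. Interferon-stimulated genes gave 12 up and 6 down of 35 (median 0.40, adjusted p = 0.157), and ATF4 and unfolded protein genes 10 up and 5 down of 24 (median 0.23, adjusted p = 0.373). The lists of DNA replication (8 up, 5 down, median 0.16, adjusted p = 0.516), histones (7 up, 2 down, and 1 and 0 adjusted over the list alone, median 0.14, 0.504), TGF-beta response (2 up, 7 down, median -0.12, 0.504), apoptosis regulators (7 up, 3 down, median 0.22, 0.299), zinc finger genes (107 up, 95 down, median 0.01, 0.93) and ribosomal proteins (7 up, 5 down, and 4 and 1 over the list alone, median 0.05, 0.792) did not pass.

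Across doses the genes past an adjusted p of 0.05 against DMSO numbered 2231 up and 2222 down at 100 nM, 3355 and 3100 at 150 nM, 3938 and 3583 at 200 nM, and 4889 and 4651 at 500 nM, of 18801 tested (n = 3 libraries per group). NF-kB genes had medians of 1.62, 2.42, 2.94 and 3.65, and mesenchymal genes -1.08, -1.34, -1.54 and -1.67, in order of dose. FN1 stood at 9483 ± 4729 (SD), 7324 ± 3922, 6176 ± 3162 and 4370 ± 949 CPM, against 24390 ± 2358 in DMSO. Replicate 1 was low at every dose, at 4411, 3144, 2946 and 3335 CPM. Replicates 2 and 3 went from 10260 and 13770 at 100 nM to 4577 and 5198 at 500 nM. At 100 nM the adjusted p of FN1 was 0.0389. FN1 no longer passed with any of 5 of the 6 libraries left out, with adjusted p from 0.023 to 0.182, the highest without 100 nM replicate 1. TWIST1 did not pass at 100 nM (-0.34, adjusted p = 0.306). At 150 nM it was lower (-0.73, adjusted p = 0.0229), lost without DMSO replicate 3 (0.0919) or 150 nM replicate 1 (0.115) or 2 (0.0779). At 200 nM it fell (-0.88, adjusted p = 0.00672). SNAI2 fell at 150 nM (-0.57, adjusted p = 0.00335) and at 200 nM (-0.73, adjusted p = 0.0004). VIM did not pass at 100, 150 or 200 nM (0.00, -0.09 and -0.10). IL8 rose at each dose, by 4.64, 6.47 and 7.25 at 100, 150 and 200 nM, with adjusted p of 0.226 and 0.0731 for the lower 2 doses under precision weights. The DMSO and dose libraries came in separately normalised parts of the deposited table, and were rescaled jointly from reads. A batch difference between those parts cannot be separated from an effect of chaetocin at day 2 by these libraries alone. The washout libraries share a part with their own DMSO cells, and their changes correlated with those of 100 nM at r = 0.795. Opposite calls were 12 and 3, against 435.9 and 330.2 expected. That argues against a batch difference as the source of the changes shared at 100 nM. For a single gene or a higher dose it stays open.

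Steps between neighbouring doses lie inside 1 part of the table. limma called 0 genes in each, 150 against 100 nM, 200 against 150 nM and 500 against 200 nM, where 797, 273 and 1380 genes had an unadjusted p below 0.05. Groups without overlap were seen in 6.5%, 4.4% and 10.6% of genes. Chance gives 10% for independent libraries, but the replicate numbers pair the doses, and a spread shared by the pairs lowers the share to expect. Log2 fold changes over those steps were -0.39, -0.15 and -0.38 for TWIST1 and -0.40, -0.22 and -0.37 for FN1, all without passing (n = 3 libraries per group). Within replicate numbers TWIST1 was lower in every pair at each step, and FN1 in every pair but that of replicate 1 from 200 to 500 nM. With the replicate block adjusted p was 0.706, 1 and 0.424 for TWIST1 and 0.743, 1 and 0.615 for FN1. With the dose libraries alone and a replicate block, 500 against 200 nM gave 60 genes, 48 up and 12 down.

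After 15 h of 80 nM chaetocin and 48 h of fresh medium, IL8 was up by a log2 fold change of 5.15 (SE 0.17, adjusted p = 5.5e-10, n = 3 libraries per group). CXCL1, a related chemokine, was up by 4.59 (SE 0.17, adjusted p = 1.1e-08), TNFAIP3, a feedback inhibitor of NF-kB, by 1.68 (SE 0.08), and HMOX1 by 3.22 (SE 0.15, adjusted p = 1.1e-08). XDH, which makes uric acid, rose by 4.24 (SE 0.21, adjusted p = 1.7e-08), and ESRP1 rose from 1 read to 129 (adjusted p = 1.6e-07). FN1 fell (-1.02, SE 0.18, adjusted p = 0.00231), as did ZEB1 (-0.70, SE 0.07, adjusted p = 4.5e-06), SPARC (-1.38, SE 0.13) and INHBB, an activin subunit (-3.21, SE 0.17, adjusted p = 2.6e-08). TWIST1 itself did not pass (0.35, SE 0.17, adjusted p = 0.131), with 538.3 against 423.9 CPM, and its adjusted p ranged down to 0.0254 over the alternatives. VIM did not pass (0.42, adjusted p = 0.104, and 0.0288 with the replicate block), and neither did SNAI2 (-0.03, adjusted p = 0.787) or CDH1 (12 against 6 reads, adjusted p = 0.197, and 0.0399 without DMSO day 4 replicate 1). EPCAM had 16 reads against 2 (adjusted p = 0.00173). Such gains from a few reads were not particular to epithelial genes, as 1113 genes silent in DMSO cells of day 2 gained 7.52 times in read density.

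After the washout 3412 genes were up and 3030 down of 17585. NF-kB genes were up in 17 of 18 cases (median 1.78, camera adjusted p = 1.9e-13, and 0.0876 with an estimated correlation), with CSF2, a myeloid growth factor, at 140 reads against 0 (n = 3 libraries per group). NRF2 genes gave 17 up and 2 down of 24 (median 0.80, adjusted p = 2.9e-07, and 0.0831 with an estimated correlation). Mesenchymal genes gave 21 down and 3 up of 38 (median -0.82, adjusted p = 1.1e-07, and 0.316 with an estimated correlation), with FBLN5, an elastic fibre protein, down (-1.77). Epithelial genes gave 10 up and 5 down of 39 (median 0.23, adjusted p = 0.235). Mitosis genes gave 23 up (median 0.61, adjusted p = 1.5e-08, and 0.393 with an estimated correlation). For apoptosis regulators the median was 0.10 and the mean -0.01. Across genes the washout changes correlated with those of 100 nM chaetocin at r = 0.795, with 1354 shared rises and 1464 shared falls, 3.61 and 3.81 times the number expected.

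Knockdown lowered SUV39H1 in HMLE-TWIST1 cells at day 2 (log2 fold change -1.40, SE 0.19, adjusted p = 5.8e-05, n = 3 libraries per group) and SUV39H2 (-1.21, SE 0.13, adjusted p = 3.3e-06). In HMLE cells at day 2 SUV39H1 fell (-1.28, SE 0.19, adjusted p = 8.7e-05), to 2.48 from 6.13 CPM. SUV39H2 was lower there (-0.39, SE 0.13, adjusted p = 0.0297), a call lost without HMLE scramble replicate 1 (0.0693) or 2 (0.0545) or knockdown replicate 1 (0.107). At day 4 in HMLE-TWIST1 cells the falls were -1.03 (SE 0.26, adjusted p = 0.00397) and -0.80 (SE 0.11, adjusted p = 1.3e-05). At day 4 in HMLE cells SUV39H2 fell (-0.50, SE 0.11, adjusted p = 0.00209, and 0.0514 with only the compared groups). SUV39H1 was lower there (-0.90, SE 0.26, adjusted p = 0.0143), lost without scramble replicate 1 (0.0533) or 2 (0.0646), without knockdown replicate 1 (0.0728) or 2 (0.0665), and with only the compared groups (0.0517).

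At day 2 the knockdown raised interferon-stimulated genes in both lines. In HMLE-TWIST1 cells MX1, an antiviral GTPase, rose by a log2 fold change of 5.90 (SE 0.13, adjusted p = 2.6e-12, n = 3 libraries per group), from 4.77 to 296.5 CPM. OAS2, a sensor of double-stranded RNA, rose by 6.22 (SE 0.25, adjusted p = 1.1e-07). In HMLE cells MX2, a relative of MX1, rose by 6.08 (SE 0.14, adjusted p = 3.8e-13), and IFIT1, which binds foreign RNA, by 6.40 (SE 0.29, adjusted p = 8.4e-07). All 37 genes of the list rose in HMLE-TWIST1 cells, with a median of 3.14 (camera adjusted p = 0.00424 with an estimated correlation). In HMLE cells 36 of 37 rose, with a median of 3.92 (0.00755 with an estimated correlation).

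In HMLE-TWIST1 cells at day 2 of knockdown, TWIST1 fell (log2 fold change -0.49, SE 0.09, adjusted p = 0.00165, n = 3 libraries per group), as did FN1 (-0.44, SE 0.05, adjusted p = 2.1e-06), SNAI2 (-0.47, SE 0.05, adjusted p = 2.7e-06) and VIM (-0.32, adjusted p = 0.00182). TNC, the matrix protein tenascin C, fell (-1.53, SE 0.05, adjusted p = 2.6e-12), as did GLUL, glutamine synthetase (-1.44, SE 0.05) and DKK1, a WNT inhibitor (-1.47, SE 0.08). ZEB1 did not pass with both lines in the fit (-0.47, adjusted p = 0.32), and passed with only the compared groups (3.2e-05). The fit of both lines shares 1 variance per gene, and ZEB1 stood at 3.12 and 2.88 CPM in HMLE scramble and knockdown cells. Whether spread at those low levels undid the call was not tested further. DSP, for the desmosome protein desmoplakin, rose by 1.00 (SE 0.05, adjusted p = 3.2e-10). CDH1 had 4 reads against 1 (adjusted p = 0.369). Mesenchymal genes gave 19 falls and 0 rises of 38 (median -0.29, camera adjusted p = 3.6e-11, and 0.0268 with an estimated correlation). Cholesterol synthesis genes gave 14 falls of 21 (16 over the list alone, median -0.36, 0.0283 with an estimated correlation), with SQLE, squalene epoxidase, at -0.88. TGF-beta response genes gave 9 falls of 22 (median -0.31, adjusted p = 1.8e-07, and 0.143 with an estimated correlation). Epithelial genes gave 3 rises and 4 falls (median 0, mean 0.02, adjusted p = 0.949). Genes called numbered 1348 up and 1478 down, and 2018 to 2666 in all with a library left out.

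In HMLE cells at day 2 of knockdown KRT10, a keratin of differentiating layers, fell (log2 fold change -3.01, SE 0.08, adjusted p = 5.1e-14, n = 3 libraries per group), from 895 to 111 CPM. DSG1, a desmosomal cadherin, fell (-2.28, SE 0.15, adjusted p = 5.2e-09), as did SPINK5, a protease inhibitor of the epidermis (-2.15, SE 0.16), LYNX1, a modulator of acetylcholine receptors (-2.12, SE 0.25, adjusted p = 1.2e-05), and KRT4 (-1.96, SE 0.17). DSP fell (-0.84, SE 0.05, adjusted p = 3.0e-09). TWIST1 (-0.57, SE 0.09, adjusted p = 0.000268, 8.92 against 13.26 CPM), FN1 (-0.42, SE 0.05, adjusted p = 2.5e-06) and VIM (-0.41, SE 0.06, adjusted p = 9.8e-05) fell in this line too. Mesenchymal genes gave 17 falls and 3 rises of 38 (median -0.27, camera adjusted p = 3.6e-05, and 0.088 with an estimated correlation). Epithelial genes gave 15 falls of 39 and 0 rises (median -0.41, camera adjusted p = 3.0e-07, and 0.00755 with an estimated correlation). Mitosis genes gave 23 rises of 27 (median 0.40, 0.03 with an estimated correlation), with CDK1, the mitotic kinase, up by 0.73 (SE 0.09). Cholesterol synthesis genes gave 18 falls of 21 (median -0.40, 0.03 with an estimated correlation). CDH1 (-0.33, adjusted p = 0.468) and EPCAM (0.63, adjusted p = 0.107) did not pass with both lines in the fit and did with only the compared groups (8.2e-05 and 4.1e-06). The fit of both lines shares 1 variance per gene. In HMLE-TWIST1 scramble and knockdown libraries CDH1 had 1 and 4 reads and EPCAM 3 and 4. Whether spread at those low levels undid the calls was not tested further. Genes called numbered 2521 up and 2621 down.

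At day 4 the interferon rise was larger in both lines. In HMLE-TWIST1 cells OAS1, a further sensor of double-stranded RNA, rose by a log2 fold change of 7.79 (SE 0.09, adjusted p = 8.8e-20, n = 3 libraries per group), MX1 by 7.36 (SE 0.09, adjusted p = 1.8e-19), and OAS2 from 0.956 to 865.5 CPM. In HMLE cells IFI6, a mitochondrial interferon target, rose by 7.75 (SE 0.09, adjusted p = 8.1e-19). The list medians were 5.55 in HMLE-TWIST1 (37 of 37 up, camera adjusted p = 2.5e-05 with an estimated correlation) and 4.82 in HMLE cells (36 up, 1.0e-05 with an estimated correlation). NF-kB genes passed with an estimated correlation in both lines (0.0113 and 0.0204). CCL5, a chemokine induced by interferon, went from 0 to 22.5 CPM in HMLE-TWIST1 cells, and BIRC3, an inhibitor of apoptosis, rose by 1.48 (SE 0.10). Apoptosis regulators also passed in HMLE-TWIST1 (10 up, 1 down, median 0.30, 0.041 with an estimated correlation) and in HMLE (9 up, 0 down, median 0.25, 0.0204 with an estimated correlation).

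**Figure D2:**
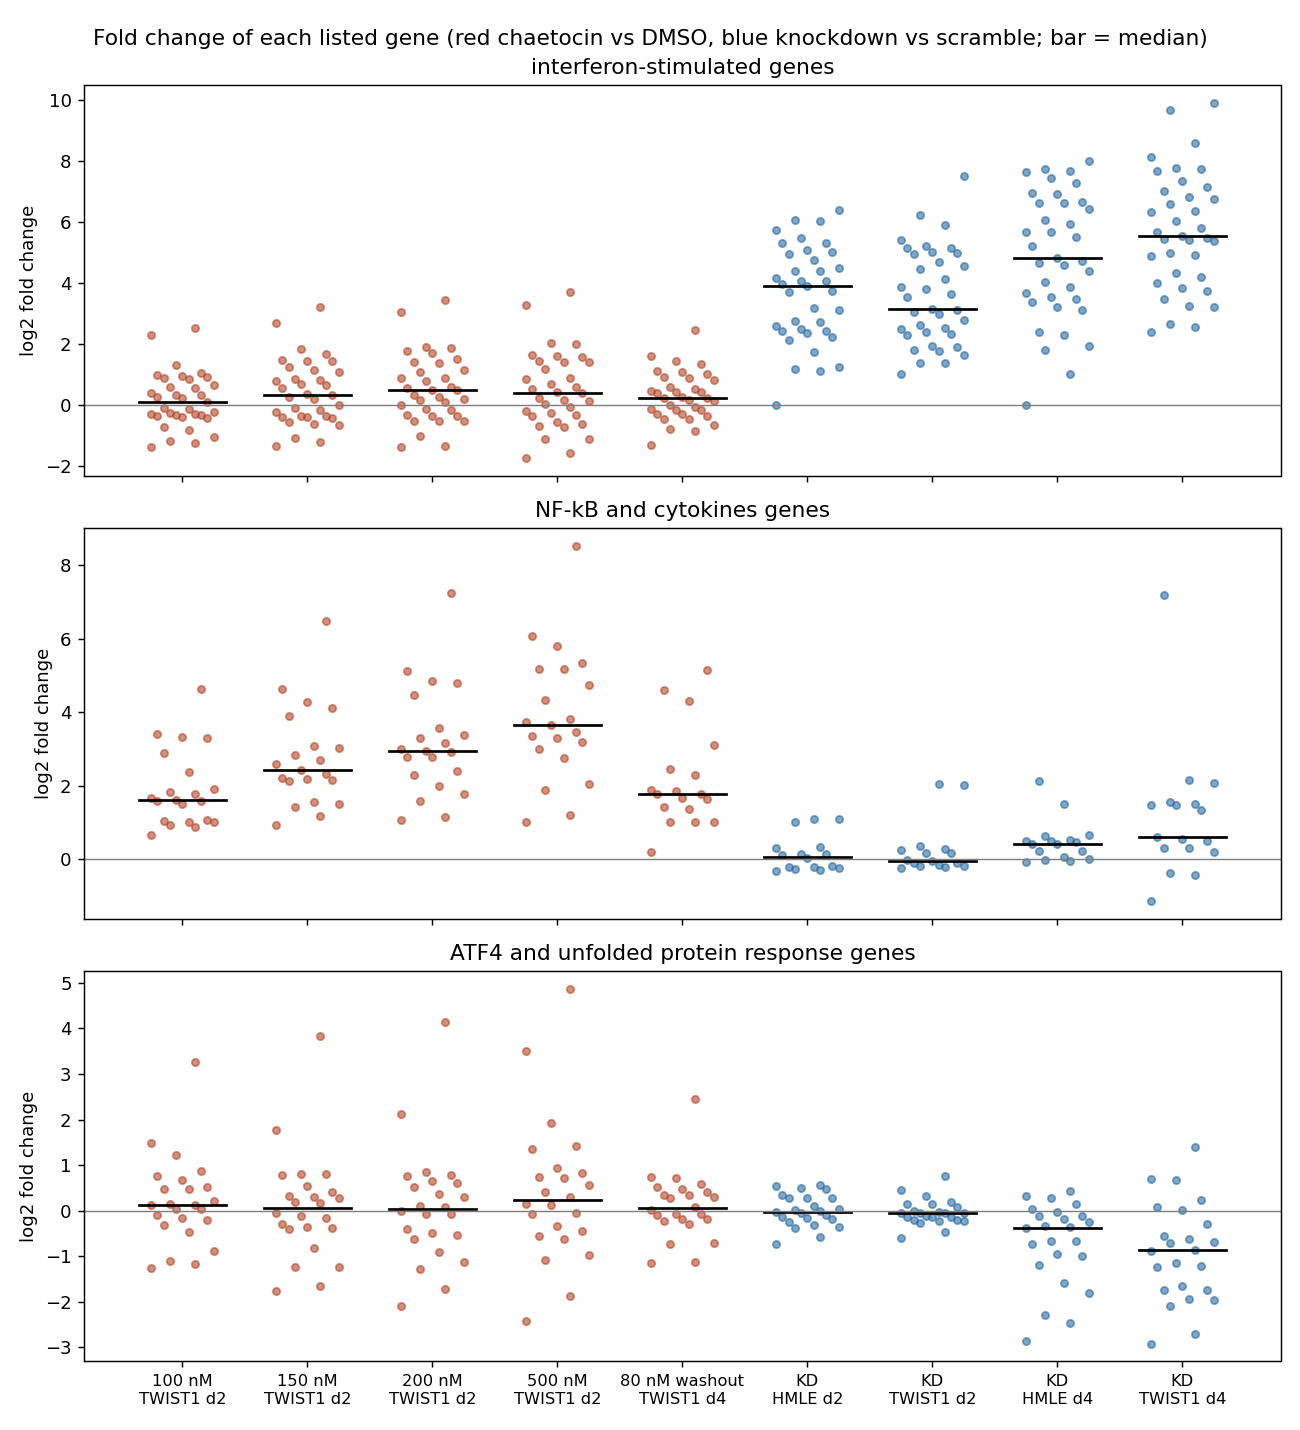
Log2 fold changes of each measured interferon-stimulated, NF-kB and ATF4 list gene, with chaetocin against DMSO and knockdown against scramble side by side. Bars are medians, and 3 libraries stand behind each group.

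FN1 fell in HMLE-TWIST1 cells at day 4 of knockdown (log2 fold change -1.20, SE 0.10, adjusted p = 1.7e-06, n = 3 libraries per group), from 15210 to 6609 CPM. VIM fell (-0.89, SE 0.21, adjusted p = 0.00818), as did TWIST1 (-0.48, SE 0.09, adjusted p = 0.00024), FAP, a protease of activated fibroblasts (-1.67, SE 0.10) and TAGLN, an actin-binding protein (-1.52, SE 0.13). SNAI2 was lower (-0.21, adjusted p = 0.00968), lost without scramble replicate 3 (0.094) or knockdown replicate 2 (0.114) or 3 (0.0569). ZEB1 (-0.27, adjusted p = 0.0992) and CDH2 (0.29, adjusted p = 0.157) did not pass. The transition factors TCF4 (1.07, adjusted p = 1.9e-09), KLF8 (1.32, adjusted p = 4.9e-06) and SOX9 (1.81, adjusted p = 0.00017) rose. CDH1 had 8 reads against 3 (adjusted p = 0.116), and DSP rose by 1.64 (SE 0.05, adjusted p = 3.5e-14). Of the other epithelial genes named, SPINT1 rose (1.11), while ITGB4 (-1.05) and LAMA3 (-0.77) fell. RPL5 and RPL4, of the large ribosomal subunit, fell (-1.83, SE 0.07) and -1.74 (SE 0.05). Ribosomal protein genes gave 70 falls of 82 and 0 rises (median -0.90, camera adjusted p = 2.3e-34, and 0.041 with an estimated correlation). ASNS, asparagine synthetase, fell (-2.92, SE 0.30, adjusted p = 7.8e-05), as did TRIB3, a stress pseudokinase (-2.70, SE 0.22, adjusted p = 2.0e-07). The ATF4 list gave 18 falls and 3 rises of 24 (median -0.87, adjusted p = 4.5e-07, and 0.229 with an estimated correlation), with HSPA5, the chaperone BiP, up by 1.40 (SE 0.05). Mesenchymal genes gave 16 falls and 5 rises of 38 (median -0.21, adjusted p = 0.00322, and 0.334 with an estimated correlation). The cholesterol synthesis genes HMGCS1 (1.34, adjusted p = 1.9e-09) and INSIG1 (1.21, adjusted p = 6.3e-09) rose. At day 2 they had fallen (-0.78 and -0.96). Genes called numbered 3422 up and 3410 down.

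In HMLE cells at day 4 of knockdown, ASNS fell (log2 fold change -2.47, SE 0.30, adjusted p = 0.0004, n = 3 libraries per group), as did STC2, a stress hormone (-2.44, SE 0.20), and KRT84, a hair keratin (-2.59, SE 0.29, adjusted p = 2.9e-05). SNAI2 rose by 0.66 (SE 0.06, adjusted p = 2.5e-07), ITGA5, the fibronectin receptor, by 1.04 (SE 0.07, adjusted p = 2.7e-09) and THY1 by 1.14 (SE 0.07, adjusted p = 2.8e-09). FN1 did not pass (0.06, adjusted p = 0.732). Mesenchymal genes gave 10 rises and 6 falls of 38 (median 0.24, camera adjusted p = 0.00675, and 0.453 with an estimated correlation). Ribosomal protein genes gave 46 falls and 1 rise of 82 (median -0.30, adjusted p = 2.9e-14, and 0.224 with an estimated correlation), and the ATF4 list 15 falls and 2 rises of 24 (median -0.37, adjusted p = 2.0e-05, and 0.433 with an estimated correlation). Epithelial genes gave 4 rises and 8 falls (median -0.18, mean -0.09, adjusted p = 0.458). Genes called numbered 2107 up and 2592 down.

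The interaction of knockdown with line was tested directly. Depth of knockdown differed too, with SUV39H2 at -1.21 in HMLE-TWIST1 and -0.39 in HMLE cells at day 2. At day 4 it stood at -0.805 and -0.503. An effect of line cannot be told apart from that of a deeper knockdown. At day 2 the effect on KRT10 was higher in HMLE-TWIST1 by a log2 fold change of 2.54 (SE 0.11, adjusted p = 2.7e-10, n = 3 libraries per group), on DSP by 1.83 (SE 0.07, adjusted p = 1.3e-10), and on TNC lower (-1.20, SE 0.08, adjusted p = 7.1e-08). The antiviral helicase gene DDX60 gained less in HMLE-TWIST1 (-2.11, SE 0.18, adjusted p = 4.7e-05), while FN1 (-0.03, adjusted p = 0.851) and TWIST1 (0.08, adjusted p = 0.762) did not differ past the threshold. Genes called numbered 1137 up and 1042 down at day 2, and 2186 and 1925 at day 4. At day 4 the effect on FN1 was lower in HMLE-TWIST1 (-1.26, SE 0.14, adjusted p = 6.8e-05), on SNAI2 (-0.87, adjusted p = 1.6e-06), on FAP (-1.53, SE 0.14) and on LAMP3, a lysosomal protein induced by interferon (-3.66, SE 0.14, adjusted p = 2.1e-11). HMGCS1, an enzyme of cholesterol synthesis, was higher by 1.67 (SE 0.13, adjusted p = 9.0e-08). At day 4 cholesterol synthesis genes gave 17 higher and 0 lower (median 0.77, 0.055 with an estimated correlation), and mesenchymal genes 19 lower and 1 higher (median -0.61, camera adjusted p = 5.6e-09, and 0.109 with an estimated correlation).

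Genes that separate the lines by at least a log2 fold change of 1 were followed as sets. At 500 nM chaetocin, of 2875 genes higher in HMLE-TWIST1, 60.7% moved toward HMLE with a median of -0.27, against -0.05 for draws matched for abundance. Of the 2627 genes lower in HMLE-TWIST1, 64.7% moved toward HMLE with a median of 0.31. For the 2227 of these that could be matched the median was 0.22, against 0.16 for the draws (0.12 to 0.19). With an estimated correlation adjusted p for the sets ranged from 0.267 to 0.343 over the 4 doses. After washout 51.7% and 53.4% moved toward HMLE (estimated-correlation adjusted p of 0.583 and 0.48). After knockdown in HMLE-TWIST1 at day 2, 66.9% of 2369 higher genes moved toward HMLE with a median of -0.14 (0.0193), and 52.2% of 2301 lower genes with a median of 0.02 (0.0214). At day 4 the figures were 55.5% (median -0.07, 0.191) and 58% (median 0.11, 0.0316). Toward HMLE refers here to control HMLE cells. Knockdown shifted HMLE cells too at day 2, with 716 falls shared by the lines against 216.1 expected. For the mesenchymal list the difference of the effect between lines was -0.05 at day 2 (camera adjusted p = 0.681).

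At day 2 in HMLE-TWIST1 cells the log2 fold changes of chaetocin and knockdown correlated over genes with r of 0.093 to 0.116 across doses. Shared falls were 2.15 times the expected number at 100 nM (406 against 189.2) and 1.76 times at 500 nM (699 against 396.3), and FN1 and TWIST1 were among the genes called down by both at 500 nM. Shared rises were 1.23 times expected at 100 nM (162 against 132) and 1.1 times at 500 nM (313 against 284.9). Genes down under chaetocin and up after knockdown also exceeded the expected number, with 229 against 171.2 at 100 nM and 398 against 358.6 at 500 nM. Genes up under chaetocin and down after knockdown fell short of it, with 121 against 145.8 and 206 against 314.8. A log2 fold change of at least 1 on both sides turned these opposite calls, with 3 against 4.2 and 9 against 14 down under chaetocin and up after knockdown, and 15 against 4 and 28 against 10.5 the other way. Shared rises were then 26 against 5.6 and 41 against 14.8, and shared falls 16 against 3 and 29 against 10. MX1 rose in both, by 2.03 at 500 nM chaetocin and 5.90 after knockdown. The knockdown responses of the lines were closer to each other, with r = 0.421 at day 2 and 0.534 at day 4, and 0.318 and 0.446 without the interferon list. Washout and day 4 knockdown gave r = 0.044 and a rank correlation of -0.014. Shared rises were 607 against 609 expected and shared falls 709 against 592.4. Opposite calls were 726 against 619 (up after washout) and 756 against 582.9 (down after washout). With that minimum shared rises were 84 against 23.4, shared falls 46 against 22.3, and opposite calls 40 against 26.1 and 28 against 20.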

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

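The tests of the interferon, ATF4 and silent-gene patterns were chosen after those patterns were seen. Those of the silent genes, and that of knockdown against scramble for the interferon genes, were also set after the values were known. The splits were set before.

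Interferon-stimulated genes such as MX1 and OAS1 rose in both lines after the duplexes against SUV39H1 and SUV39H2. A response to any transfected duplex is argued against as the cause, since scramble cells also received a duplex. The list medians of knockdown over scramble inside 1 part of the table were 3.92 in HMLE and 3.14 in HMLE-TWIST1 cells at day 2. Those medians are the pattern itself, so the argument rests on the scramble cells as its control. Against DMSO cells of day 2 the scramble medians were -0.51 and -0.15, but those libraries lie in separately processed parts, so a batch difference could hide a rise there. Loss of SUV39H1/H2 activity could open silenced repeats whose RNA is sensed, but under chaetocin the list median reached only 0.49, at its highest over 5 comparisons, and 0.12 at its lowest. That leaves loss of SUV39H1/H2 activity open, as chaetocin may also act on other targets. A response to the sequence or dose of the particular duplexes was not tested, and duplexes of other sequences with the same targets would tell these apart.

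ATF4 genes such as ASNS, TRIB3 and PSAT1 were lower in knockdown than in scramble cells at day 4. A rise in the scramble cells between day 2 and day 4 fits, with list medians of 0.76 in HMLE and 1.25 in HMLE-TWIST1 scramble cells, against 0.19 and 0.16 in knockdown cells. The pattern may therefore be an induction, as by amino acid use in the medium, that the knockdown cells lacked, and not a fall from a basal level. Slower growth or fewer cells after the interferon response could leave more nutrients, which cell counts would show and which was not tested here. In HMLE cells at day 4 of knockdown mitosis genes gave 2 rises and 0 falls of 27 (median 0.12, camera adjusted p = 0.0583). In HMLE-TWIST1 cells at day 4 the mitosis genes CCNB1 (-0.49) and TPX2 (-0.41) fell. The DNA replication genes PCNA (0.39), FEN1 (0.49), GINS1 (0.45) and CCNE2 (0.34) rose there, so growth cannot be read from these genes.

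Genes silent in HMLE-TWIST1 DMSO cells of day 4, 1083 in number, gained reads under chaetocin, at 8.4, 15.7, 20.5 and 34.6 times the density of DMSO day 2 cells at 100, 150, 200 and 500 nM. Only genes listed in both the DMSO and dose parts were counted, and the dose part has its own gene filter. That favours genes with reads under chaetocin, so the size of the gain may be biased upward. The gain may come from separate processing of the dose libraries, but the washout libraries, processed with their own DMSO cells, also gained 7.52 times over 1113 genes. Genes silent in DMSO cells can enter that part through the washout libraries, which may bias this gain upward too. A uniform background such as genomic DNA would give all genes a similar density, yet 53.4% lay below and 29.4% above it at 500 nM by exact Poisson intervals. Those cover counting error only, and with the dispersion between the replicates of these genes (0.176, negative binomial) 44.9% lay below and 24.8% above it. That argues against a uniform background as the whole of the gain. The pooled density includes any induced genes, so a uniform background beneath them cannot be excluded, and one uneven between genes was not tested. The 136 genes expressed in HMLE cells gained 24.4 times at 500 nM, from 153 reads in DMSO cells of day 2 to 2823. Their median stayed at 0.0463 RPKM, against 16.3 in HMLE DMSO cells of day 4, and 20.6% had no read. DDX4, PTPRC and ERG of other lineages rose, but such genes enter through the dose libraries, which favours rises. Loss of H3K9 methylation at these genes is a candidate explanation that a map of that mark would test, as is a stress response that loosens transcription in general.

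The dose libraries also list 1711 genes that the other parts do not, and 1667 of them had 3 or more reads at 500 nM, against 1410 at 100 nM. No DMSO value stands beside them.

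The knockdown effect differed between lines in 2179 genes at day 2 and 4111 at day 4. SUV39H2 was also knocked down deeper in HMLE-TWIST1 cells, which cannot be told apart from line. At day 2 the difference of HMLE-TWIST1 minus HMLE was -0.82 for SUV39H2 (adjusted p = 0.00632) and -0.39 for SNAI2 (adjusted p = 0.00116). It was 0.46 for the epithelial list and -0.60 for the mitosis list (camera adjusted p with an estimated correlation of 0.0158 for each). All 39 epithelial genes were lower in HMLE-TWIST1 scramble cells (median -7.78), with 1 read of CDH1 and 3 of EPCAM. Genes so near 0 have little room to fall there, so the epithelial difference may reflect the fall in HMLE cells alone. At day 4 the difference between lines was -1.26 for FN1, -0.87 for SNAI2, -0.67 for ZEB1 and -0.62 for TWIST1. ZEB1 alone did not pass in HMLE-TWIST1 cells (-0.27, adjusted p = 0.0992). In HMLE cells it rose from 99 reads to 138 (0.40, adjusted p = 0.0228). VIM differed by -1.11 (adjusted p = 0.0251, and 0.0621 without HMLE knockdown replicate 3, the highest of 8 libraries that undo the call). CDH2 differed by 0.76 (adjusted p = 0.0206, and 0.0537 without HMLE-TWIST1 scramble replicate 2 or 0.0533 without knockdown replicate 3). Its HMLE side rests on 33 reads after knockdown against 45 in scramble cells, and that of VIM on 122 against 101.

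Between day 2 and day 4 the knockdown effect differed in 3751 genes in HMLE-TWIST1 and 3297 in HMLE cells. In HMLE-TWIST1 cells the difference of day 4 minus day 2 was -0.75 for FN1 and 0.27 for SNAI2. The list medians were 0.43 for transition factors, 1.96 for interferon-stimulated genes, 0.53 for NF-kB genes, 1.01 for cholesterol synthesis and -1.08 for ribosomal proteins (adjusted p of 0.000351 to 0.0152 with an estimated correlation). In HMLE cells the difference was 0.46 for FN1, 0.70 for TWIST1 and 0.72 for SNAI2. The list medians were 0.35 for epithelial, 0.60 for mesenchymal, 0.45 for transition factors, 1.17 for interferon-stimulated and 0.43 for NF-kB genes (0.00425 to 0.0259 with an estimated correlation).

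Relabelling the libraries of each comparison gave 10 splits of 3 against 3, too few for a share below 0.05. Between the lines the real split called 10229 and 11100 genes in DMSO at day 2 and day 4 and 12145 and 12680 in scramble cells, with only the compared groups fitted, and 1 split of 10, the real grouping, reached that number. The doses called 3073, 5708, 6516 and 9023 genes, the washout 6634, and the knockdowns 2981 and 8039 in HMLE-TWIST1 at day 2 and day 4 and 3959 in HMLE at day 4. In all of these the highest other split called 0. For knockdown in HMLE at day 2 the real split called 5293 and the highest other 209. In the steps between doses 10 of 10 splits reached the real count of 0, and the highest other called 0, 0 and 32. Any split reaches a count of 0, and these splits ignore the pairing by replicate number, so they say nothing about those steps.

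For the differences of effects 3 of 100 splits reached the real 2179 genes at day 2 and 3 reached 4111 at day 4, with 12777 and 12993 in the highest other split. Between days 2 splits reached 4398 in HMLE-TWIST1 and 2 reached 2952 in HMLE cells, with 5061 and 3416 in the highest other. Such splits mix lines or days, so their larger counts reflect that structure of the samples.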

How the results depend on the processing

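Alternatives of precision weights, prior counts, deposited values, dose libraries alone, washout overlaps and matched draws were tests chosen after the results were seen. DESeq2 was named in the design and not run, although the recovered reads would allow a test for counts. No named gene changed direction, and 1806 of 1811 named values held with median-of-ratios scaling, 1803 with no filter, 1804 with the replicate block, 1740 of 1811 with voom weights and 1542 of 1795 with all 51 libraries in 1 fit. With all 51 libraries in 1 fit fewer genes were called for knockdown at day 2 in HMLE (3334) and HMLE-TWIST1 (1245), for the difference between lines at day 2 (742) and day 4 (2412) and for the difference between days in HMLE-TWIST1 (2073) and HMLE (1330), and 210 were called for 500 against 200 nM. With a library left out, 150 against 100 nM gave 0 to 1 gene (1 without 100 nM replicate 2) and 500 against 200 nM gave 0 to 9 (9 without 500 nM replicate 3). With the replicate block and the dose libraries alone 500 against 200 nM gave 60. The cause of these changes was not tested. The pairing check failed in the other comparisons, with r as low as -0.49.

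Of 205 list calls 48 held with an estimated correlation. Movement of genes higher in HMLE-TWIST1 at 100 nM was -0.09 in sets with no fold-change minimum and -0.23 in sets from the comparison's own control libraries, both passing by fry where the main sets did not. For genes lower in HMLE-TWIST1, sets with no fold-change minimum gave medians of 1.3e-15, 0.01 (0.006), 0.01 (0.011) and 0.04 (0.038) at 100, 150, 200 and 500 nM, weaker than with the minimum. After washout genes lower in HMLE-TWIST1 lost their rise with no fold-change minimum (median 0, against 0.04 with a fry adjusted p of 0.0113), so no direction was left, while genes higher in it had -0.13 in sets from the comparison's own control libraries. Sets from own controls share libraries with the treatment comparison, which by construction biases them toward HMLE.

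With an absolute log2 fold change of at least 1, shared calls of chaetocin and knockdown at day 2 were 4.67, 4.12, 3.84 and 2.78 times expected for rises and 5.41, 4.23, 3.3 and 2.91 for falls at 100, 150, 200 and 500 nM. Opposite calls, up under chaetocin and down after knockdown, were also above expectation, at 15, 23, 27 and 28 against 4, 6.7, 8 and 10.5. The reverse gave 3, 3, 3 and 9 against 4.2, 6.6, 8.5 and 14. Shared calls were 3.58 and 2.06 times expected for washout and day 4 knockdown, with opposite calls of 40 against 26.1 and 28 against 20, and 12.1 and 14.2 for washout and 100 nM. For knockdown in the lines they were 43.6 and 5.23 at day 2 and 13.1 and 7.33 at day 4. The cause of these rises was not tested.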

Other observations

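The tests in this part were chosen after the results were seen, and no new threshold was set for them. The AP-1 subunits FOSB and FOSL1 rose together with IL8 and IL6 at 500 nM chaetocin, FOSB from 15 to 365 reads. The cyclin inhibitor RNA CDKN1A was lower in HMLE-TWIST1 than in HMLE scramble cells at day 4, at 86.8 against 1257 CPM, in the libraries where all 27 mitosis genes were higher. In scramble cells of day 2, 26 of 27 mitosis genes were already higher (median 1.83), against 1 in DMSO cells of day 2. HMLE cells that divide less than HMLE-TWIST1 cells would give lower mitosis and higher CDKN1A RNA, and a count of cells was not analysed here.

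Desmoplakin RNA (DSP) moved in opposite directions on knockdown at day 2, by 1.00 in HMLE-TWIST1 and -0.84 in HMLE cells, with a difference of 1.83 (SE 0.07, adjusted p = 1.3e-10). FN1 fell under chaetocin, after washout and after knockdown in HMLE-TWIST1 cells, and by -0.42 after knockdown at day 2 in HMLE cells. CDH1 stayed at 77 reads or fewer in the treated HMLE-TWIST1 groups, against 21951 in HMLE DMSO cells of day 2. VIM fell after knockdown at day 2 in both lines and did not pass under chaetocin, a difference that was not tested. The interferon list had a median of 0.49 under 200 nM chaetocin and 3.14 after knockdown at day 2. The test for a shared path through SUV39H1/H2 would be chaetocin in cells that already lack both enzymes.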
